A study of Mus musculus with 6 samples.

How the data were processed

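RNA of 6 leukemias, 3 labelled Runx1-KO and 3 labelled Control, had been extracted with a spin-column kit, converted to cDNA, fragmented and labelled with biotin by the NuGEN Ovation system, per the labels' protocols. Probe set names were those of a 1-colour Affymetrix mouse array with 45101 probe sets. The deposited values were linear probe set intensity values, already on a common scale and with a floor of 1, below which 1 value lay. How the authors summarised probes, subtracted background and normalized the arrays is not given in the sources used here, nor are detection calls or scan dates. Median intensity per array ranged from 24.4 to 26.0. All 6 columns were mapped to samples by their names.

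Gene names came from the platform's annotation. Of the 45101 probe sets, 34958 had 1 symbol, 932 had several and 9211 had none, including 64 control probe sets. The symbols of 34754 were looked up by Entrez identifier in a RefSeq gene table and 0 changed. Probe sets with several symbols or none were left out of the gene table. For the 9012 genes with more than 1 probe set, the one with the highest mean over all 6 arrays was used, which gave 18194 genes. Probe sets of a gene could disagree, and where they did the text says so. Runx2 was not analysed here.

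Intensities were taken to log2 and the groups compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with no covariate and no filter, and with Benjamini-Hochberg adjustment at 0.05 over all genes. Differences are Runx1-KO minus Control on the log2 scale with the moderated standard error, and folds were computed from them. Gene lists were tested against all other genes with limma's camera at its preset correlation of 0.01, for lists with at least 4 measured genes, with adjustment over the lists. The same test with an estimated correlation left 0 of 26 lists past the threshold, with a lowest adjusted p of 0.272. The rotation test fry asks whether a list's genes moved one way and does not compare them with other genes. It gave 2 lists, MLL fusion targets (fry adjusted p = 0.00347) and sex-linked genes (fry adjusted p = 2.43e-05). Its mixed form, which allows either direction, gave 9.

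The design, the test, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The 26 lists covered the RUNX and CBF family, known RUNX1 targets, MLL fusion targets, stem and progenitor markers, primary granule genes, mature neutrophil genes, monocyte and macrophage genes, dendritic cell and MHC class II genes, eosinophil, basophil and mast cell genes, erythroid genes, megakaryocyte and platelet genes, B cell genes, T and NK cell genes, stromal and endothelial genes, p53 targets, the BCL2 family, G1/S and G2/M genes, ribosome biogenesis and MYC targets, ribosomal proteins, oxidative phosphorylation, interferon response, NF-kB targets, immediate early and stress genes, sex-linked genes, and cytokine receptor and signalling genes. Named genes were Runx1, Runx3 and Cbfb, then the 10 largest rises and the 10 largest falls past the threshold. Where fewer than 10 passed, genes of lowest p whose groups did not overlap filled the places and were described as not past it, and names that are only identifiers were passed over. From each list at most 4 members past the threshold over all genes or over the list alone were named by lowest p, or else the member of lowest p. Hoxa9, Meis1, Bcl2 and Alas2, and all genes named only in the closing section, were chosen after their values were seen.

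A background limit was set after the data were seen, as the highest of 27 spike-in probe sets without target on each array, 14.1 to 22.5. A gene at or below the limit on every array of a group was called dim there. A gene dim in 1 group received a lower bound, the mean log2 level of the bright group against that of the dim group with each array raised to its limit, and no fold where the bound was under 1 or where both groups were dim, as for 5434 genes. Where the lower group was dim on only some arrays, those arrays were raised to their limits in the same way, the fold is given as at least that value, and the text says how many arrays lay above background. List medians were also computed with such genes at their bound, or at 0 where no bound could be stated.

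The alternatives were quantile normalization, median centring, 2 filters on dim genes, all probe sets or their mean per gene, a variance trend with robust fitting, array weights, unmoderated statistics, an adjusted p under 0.1, a fold of at least 2, the replicate number as a block, leaving out each array, and the 2 other list tests. Chosen after the data were seen were an offset of 16 before the log, leaving out both arrays numbered 1, leaving out the 4 measured genes of the sex-linked list, and 5 further gene lists (X-linked genes that escape inactivation, a second list of mature blood neutrophil genes, and genes of cholesterol synthesis, of serine synthesis and ATF4 response, and of glycolysis). Over all genes, the median log2 difference was -0.01, and quantile normalization and median centring both gave a median within 0.01 of 0.

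The steps were tested on simulated data with 18194 genes of which 200 were changed, in 5 runs. At these 6 arrays 3.58% of genes changed 2-fold were recovered, 66.9% of those changed 4-fold and 87.3% of those changed 8-fold, with 6.2 false calls per run. The list of ribosomal protein genes, shifted by 1 on the log2 scale, was called in 5 of 5 runs, with 1 call of another list. No other list and no smaller shift was planted. The runs therefore do not show how often dim or more variable lists, or smaller shifts, would be found. Simulated genes were drawn independently of each other, whereas the estimated correlation within real lists reached 0.73 (G2/M and mitosis genes). These runs therefore do not give the rate of false list calls in the real data. The single-gene test of Runx1 was an exact permutation test, for which 3 arrays against 3 allow no p below 0.1.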

Results

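Gene expression was measured in mouse leukemias driven by MLL-ENL, a fusion of the histone methyltransferase MLL with the transcription elongation factor ENL. Bone marrow carrying either an intact or an excised Runx1 gene received MLL-ENL, was transplanted into congenic mice, and the leukemic cells were collected once the recipients were moribund. Runx1 encodes a transcription factor needed for the emergence of blood stem cells and for megakaryocyte and lymphoid development. The 3 arrays labelled Runx1-KO and the 3 labelled Control each came from independent leukemias of the C57BL/6 strain, and the comparison asked how loss of Runx1 altered the leukemia transcriptome. Each array carried 45101 probe sets, from which 18194 genes were taken with 1 probe set each. Median intensities ranged from 24.4 to 26.0, and 57.4% to 64.7% of genes lay above the background limit of their array. Spearman correlations across genes ranged from 0.950 to 0.965 within the arrays labelled Runx1-KO, from 0.964 to 0.972 within Control and from 0.949 to 0.963 between the groups. With 3 arrays per group, the number of arrays limited the precision.

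Runx1 signal was not lost in the arrays labelled Runx1-KO. Its intensity was 1128, 1573 and 1630 in the 3 arrays labelled Runx1-KO and 680.3, 1022 and 850.0 in the 3 labelled Control, a log2 difference of 0.76 ± 0.25 (SE, n = 3 per group), or 1.70-fold higher, with a limma adjusted p of 0.322. All 6 Runx1 probe sets were higher in the arrays labelled Runx1-KO, by 1.70-fold to 3.18-fold, and in 5 of the 6 the groups did not overlap. An exact two-sided permutation test of the log2 level gave p = 0.1, the smallest value that 3 arrays against 3 allow. The sources used here do not give the position of these probe sets relative to the excised part of the gene. A probe set outside that part checks nothing, so Runx1 did not settle the labels, and every direction below refers to arrays as labelled. The related gene Runx3 differed by 0.33 ± 0.27 on the log2 scale (adjusted p = 0.652), and Cbfb, which encodes the shared binding partner of RUNX proteins, by -0.38 ± 0.16 (adjusted p = 0.413). Of the 6 measured genes of the RUNX and CBF family, 0 passed over all genes and 0 passed when adjusted over the list alone, with a median log2 difference of 0.12 and a camera adjusted p of 0.645. As a list the family passed only with all probe sets (median 0.23, adjusted p = 0.0284), where Runx1 counted with its 6 probe sets, and its median ran from 0.02 to 0.29 over the alternatives.

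The groups differed in sex-linked genes. Eif2s3y, a Y-linked translation factor gene, was at least 36.8-fold lower in the arrays labelled Runx1-KO (limma adjusted p = 0.000761). The Y-linked histone demethylase gene Kdm5d (at least 4.83-fold, adjusted p = 0.00901) and the Y-linked gene Uty (at least 2.19-fold, adjusted p = 0.0124) were also lower. All 3 genes were below the background limit in every array labelled Runx1-KO. Xist, the RNA that coats the inactive X chromosome of female cells, had an intensity of 1624, 1857 and 1895 in the arrays labelled Runx1-KO and of 330.8, 85.4 and 25.3 in Control 1, 2 and 3. Its log2 difference of 4.32 ± 0.87 did not pass over all genes (adjusted p = 0.190) but passed when adjusted over the list alone (adjusted p = 0.00229). Over the 4 measured sex-linked genes, 3 were lower over all genes and 4 passed when adjusted over the list alone. The median log2 difference was -3.49, or -1.70 with genes below background set to their bound, and the camera adjusted p was 6.54e-05, against an adjusted p = 0.272 with an estimated correlation. With an offset of 16 before the log the median was -1.84. Every array labelled Runx1-KO thus had high Xist and background Y-linked signal, so sex and genotype coincided in all further comparisons.

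**Figure D1:**
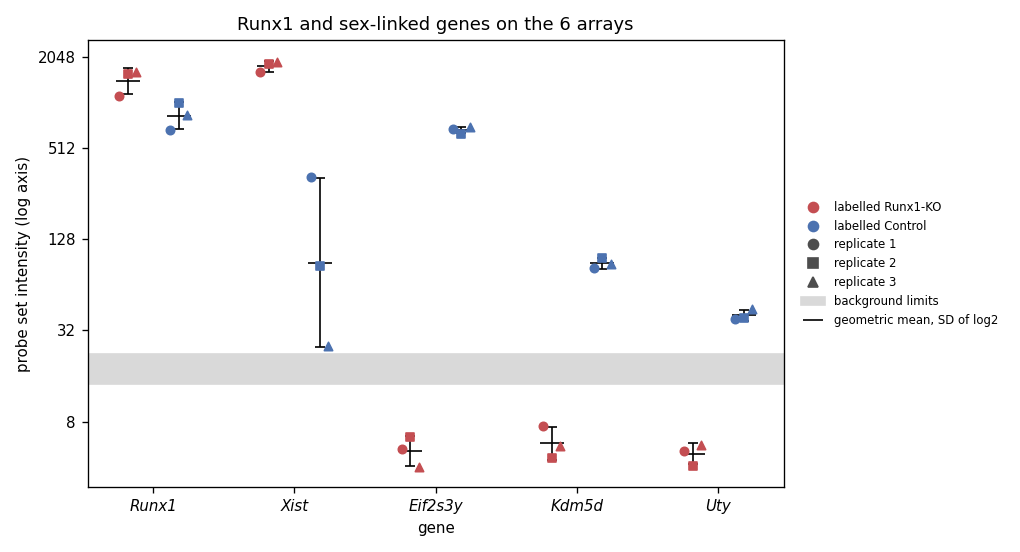
Intensity (log axis) of Runx1 and 4 sex-linked genes on each of the 6 arrays, with the geometric mean and the SD of log2 values per group and the range of the arrays' background limits in grey (14.1 to 22.5). Runx1 was higher in all 3 arrays labelled Runx1-KO, Xist lay between 1624 and 1895 there, and the 3 Y-linked genes lay below background there.

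Among 18194 genes, 6 were higher and 10 lower in the arrays labelled Runx1-KO, and in all 16 the groups did not overlap. The largest rise was in Eya1, which encodes a phosphatase and transcriptional co-activator partnering homeobox proteins and belonged to the MLL fusion target list. It was at least 24.0-fold higher (fitted log2 difference 4.78 ± 0.19, adjusted p = 0.00145), at a geometric mean intensity of 433 against 15.8, with 2 of 3 Control arrays above background. Lrg1, a secreted glycoprotein stored in neutrophil granules, rose 23.2-fold (4.53 ± 0.45, adjusted p = 0.0486). Phgdh, the enzyme that commits glycolytic carbon to serine synthesis, rose 3.77-fold (1.92 ± 0.18, adjusted p = 0.0423) with 4 of 4 probe sets higher. Reck, a membrane-anchored inhibitor of matrix metalloproteinases, was at least 4.97-fold higher (adjusted p = 0.0396). The adhesion molecule gene Mcam (adjusted p = 0.0491) was below background in Control and above it in 1 of 3 arrays labelled Runx1-KO, which left no fold to state, and the egg coat gene Zp1 (adjusted p = 0.0423) was below background in both groups.

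Of the 10 genes that fell, 3 were the Y-linked genes. Hpse2, which encodes a heparan sulfate-binding relative of heparanase, fell 15.4-fold (-3.95 ± 0.21, adjusted p = 0.00564), from a geometric mean intensity of 429 to 27.8. Nrp1, a co-receptor for semaphorins and vascular endothelial growth factor, was 8.07-fold lower on its brightest probe set (-3.01 ± 0.24, adjusted p = 0.0266), although 1 of its 4 probe sets was higher. In Runx1-KO 1, 2 and 3 it stood at 32.0, 19.9 and 25.3, against background limits of 17.0, 19.6 and 18.6. Hpse2 stood at 27.0, 31.6 and 25.2 there, so both folds rest on signal near background. F7, coagulation factor VII, was 6.56-fold lower (-2.71 ± 0.22, adjusted p = 0.0269), and Cacna1f, an L-type calcium channel subunit, 4.48-fold lower (-2.16 ± 0.18, adjusted p = 0.0309). Dguok, the mitochondrial deoxyguanosine kinase, was at least 3.86-fold lower (adjusted p = 0.0486). Scg3 (adjusted p = 0.0242) and the manganese transporter gene Slc30a10 (adjusted p = 0.0431) were below background in both groups, so no fold was stated.

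The next genes by p in the higher direction did not pass over all genes. Cxcr2, the chemokine receptor that draws neutrophils into blood and tissue, had a fitted log2 difference of 2.72 ± 0.28 (adjusted p = 0.0523), and Slc2a3, the glucose transporter GLUT3, one of 2.61 ± 0.28 (adjusted p = 0.0593). Dmkn had a log2 difference of 3.69 ± 0.38 (adjusted p = 0.0523), and the epidermal gene Lce1b (adjusted p = 0.0513) was below background in both groups. At an unadjusted p under 0.05 there were 2298 genes, 1022 higher and 1276 lower. The groups did not overlap in 20.9% of genes, where chance gives 10% on average. Genes are correlated across arrays and the share in other splits was not computed, so this excess was not tested. With any 1 of the 6 arrays left out, 1 gene remained higher and 1 or 2 remained lower, so the count rested on all 6 arrays, and Eya1 and Eif2s3y passed in each of those 6 fits. With the 4 measured genes of the sex-linked list left out before adjustment, 1 gene was higher and 5 were lower. These were Eya1 and Hpse2, Nrp1, F7, Scg3 and Cacna1f, while Lrg1 (adjusted p = 0.0604), Phgdh and Reck (adjusted p = 0.0560 for both) no longer passed. Other genes of the sex chromosomes stayed in that fit, so it does not show that the remaining calls were free of sex linkage.

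Genes of mature neutrophils were higher in the arrays labelled Runx1-KO. Of 21 measured members, 19 were higher and 2 lower, 0 passed over all genes, 7 rose when adjusted over the list alone and 14 did not. The median log2 difference was 1.04, or 0.92 with dim genes at their bound (camera adjusted p = 2.20e-09, and adjusted p = 0.350 with an estimated correlation). Il1r2, the decoy receptor for interleukin-1, was 9.35-fold higher (3.22 ± 0.44, list-alone adjusted p = 0.00287), and the granule protein gene Ngp 4.54-fold higher (2.18 ± 0.35, list-alone adjusted p = 0.00451). Cxcr2, above background in 1 of 3 Control arrays, was at least 5.84-fold higher (list-alone adjusted p = 0.00110), and the acute-phase gene Orm1 at least 1.89-fold higher (list-alone adjusted p = 0.0103). The list median was 0.63 without Control 2 and 0.68 with all probe sets. The ratio of 3' to 5' Gapdh signal, a measure of RNA degradation, was 7.10 in Runx1-KO 1 against 2.67 to 3.02 in the other arrays, and the list median was 0.75 without that array. Of the primary granule genes, which mark earlier promyelocytes, 0 of 11 passed over all genes or adjusted over the list alone, and the median was -0.04 with a mean of 0.30 (camera adjusted p = 0.559), or 0.14 without Control 2 (adjusted p = 0.0508) and -0.21 without both arrays numbered 1. Fcnb had the lowest p of that list, at 1.43 ± 0.42 (list-alone adjusted p = 0.0817). The difference between the 2 lists was not tested.

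Megakaryocyte and platelet genes were also higher. Of 19 measured members, 17 were higher and 2 lower, 0 passed over all genes, 3 rose when adjusted over the list alone and 16 did not. Across the list the median log2 difference was 0.74, or 0.29 with dim genes at their bound (camera adjusted p = 0.000140, and adjusted p = 0.350 with an estimated correlation). The median was 0.38 with array weights, 0.32 with the offset and 0.49 without both arrays numbered 1. The members that rose were Thbs1, a matrix glycoprotein released by activated platelets (at least 7.42-fold, list-alone adjusted p = 0.0286), Selp, which encodes P-selectin (at least 4.63-fold, list-alone adjusted p = 0.0286), and F2r, the thrombin receptor (at least 2.12-fold, list-alone adjusted p = 0.0464). Thbs1 was above background in 1 of 3 Control arrays, and Selp and F2r in 2 of 3.

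Monocyte and macrophage genes were lower in the arrays labelled Runx1-KO. Of 29 measured members, 23 were lower and 6 higher, 0 passed over all genes, 7 fell when adjusted over the list alone and 22 did not. The median log2 difference was -0.47, or -0.28 with dim genes at their bound (camera adjusted p = 0.000239, and adjusted p = 0.653 with an estimated correlation). Among them, Adgre1, which encodes the macrophage surface protein F4/80, had a log2 difference of -1.33 ± 0.23 (list-alone adjusted p = 0.0166), and Mpeg1, a pore-forming protein of macrophages, one of -0.99 ± 0.18 (list-alone adjusted p = 0.0166). Ms4a6c followed at -1.15 ± 0.27 and Csf1r, the receptor for macrophage colony-stimulating factor, at -0.87 ± 0.21 (list-alone adjusted p = 0.0358 for both). The list median was -0.08 without Control 1, -0.73 without Control 2 and -0.27 without both arrays numbered 1. Csf1r also stood on the list of known RUNX1 targets, of which 0 of 22 passed over all genes or adjusted over the list alone (median 0.04, or 0 with dim genes at their bound and -0.12 to 0.23 over the alternatives, camera adjusted p = 0.592). Dendritic cell and MHC class II genes had a median of -0.48, with 0 of 16 past over all genes or adjusted over the list alone (camera adjusted p = 0.101), but 7 of the 16 were below background in both groups and the median was 0.00 with dim genes at their bound and -0.16 with the offset. That list passed without Runx1-KO 2 (median -0.67, adjusted p = 0.0132) and without Control 2 (median -0.70, adjusted p = 0.00767), and its median ran from -0.99 over the brighter genes to -0.09 without both arrays numbered 1, with -0.31 without Control 1. The lowest p among them was that of H2-DMa, at -1.34 ± 0.44.

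**Figure D2:**
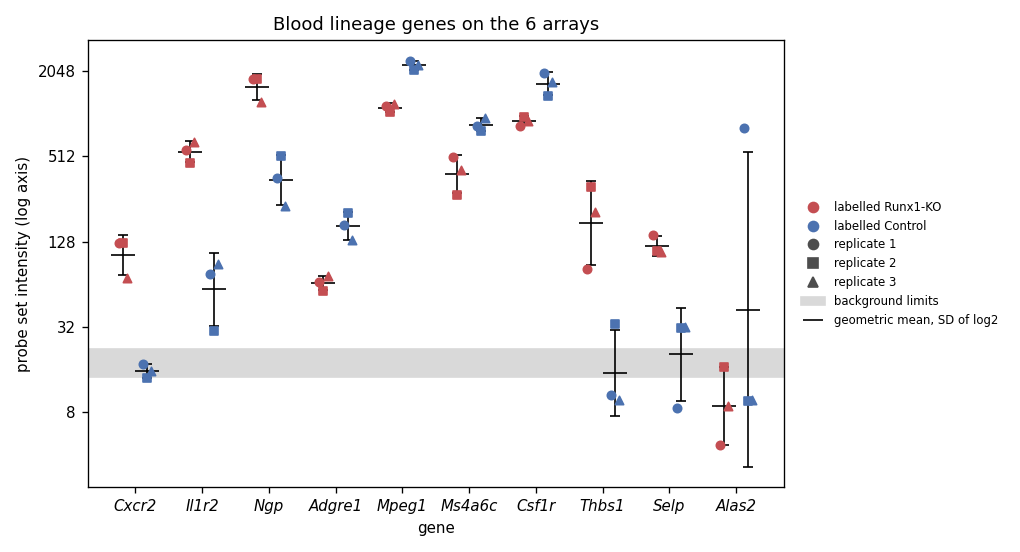
Intensity (log axis) of 10 blood lineage genes on each of the 6 arrays, with the geometric mean and the SD of log2 values per group and the range of background limits in grey (14.1 to 22.5). The neutrophil genes Cxcr2, Il1r2 and Ngp and the megakaryocyte genes Thbs1 and Selp were higher, and the monocyte genes Adgre1, Mpeg1, Ms4a6c and Csf1r lower, in all 3 arrays labelled Runx1-KO, while the erythroid gene Alas2 stood at 814.5 in Control 1 alone.

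T and NK cell genes were lower as a list but mostly near background. Of 23 measured members, 18 were lower, 0 passed over all genes, 5 fell when adjusted over the list alone and 18 did not, while 6 were below background in both groups and 8 in 1 group. The median log2 difference of -0.81 became 0 with dim genes at their bound (camera adjusted p = 0.000271, and adjusted p = 0.350 with an estimated correlation). The granzyme gene Gzma (at least 1.23-fold lower), Cd5 (at least 1.20-fold) and Cd3e (at least 1.06-fold), which encode T cell surface proteins, were below background in all arrays labelled Runx1-KO and above it in 2 of 3 Control arrays, and Gata3 was below background in both groups. The median was -0.44 without Control 1, -0.45 without both arrays numbered 1, -0.53 with all probe sets, -0.30 with the offset and 0.27 over the brighter genes only, where the call ended. B cell genes had a median of 0.10, or 0 with dim genes at their bound and -0.21 to 0.43 over the alternatives, with 0 of 21 past over all genes or adjusted over the list alone (camera adjusted p = 0.678), and the surrogate light chain gene Vpreb1 had the lowest p (at least 1.85-fold lower, with 1 of 3 arrays labelled Runx1-KO above background). Eosinophil, basophil and mast cell genes had a median of 0.01, or 0 with dim genes at their bound and -0.10 to 0.18 over the alternatives (camera adjusted p = 0.979) and 0 members past over all genes, and the member that passed over the list alone, Ccr3, was below background in both groups. Stromal and endothelial genes had a median of 0.16, or 0 with dim genes at their bound and -0.10 to 0.32 over the alternatives (camera adjusted p = 0.411), with 0 of 22 past on either adjustment and the lowest p in Esam, which was below background in both groups.

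Erythroid genes stood apart in a single array. Alas2, the first enzyme of heme synthesis in red cells, had an intensity of 814.5 in Control 1 and of 4.70 to 16.6 in the other 5 arrays, and 17 of 18 erythroid genes were highest in Control 1. The list median was -1.06, or -0.35 with dim genes at their bound (camera adjusted p = 0.0427, and adjusted p = 0.840 with an estimated correlation). It was 0.16 without Control 1 (adjusted p = 0.414). The call also ended without Runx1-KO 1 (adjusted p = 0.238) and without Runx1-KO 3 (adjusted p = 0.107), over the brighter genes (median -0.54, adjusted p = 0.681), without the dimmest genes (adjusted p = 0.0872), with array weights (adjusted p = 0.162), with the ordinary statistic (adjusted p = 0.161) and without both arrays numbered 1 (adjusted p = 0.264). The median was -1.71 without Control 2 and -1.94 without Control 3. Members past over all genes or adjusted over the list alone numbered 0, and the lowest p was that of Epor, the erythropoietin receptor gene (list-alone adjusted p = 0.658), which was above background in 1 of the 6 arrays.

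MLL fusion target genes moved in both directions, with a median above 0. Of 22 measured members, 1 rose over all genes, 3 rose and 1 fell when adjusted over the list alone, and 18 did not pass. Their median log2 difference was 0.29, or 0.28 with dim genes at their bound (camera adjusted p = 0.0169, and adjusted p = 0.350 with an estimated correlation). Besides Eya1, Cpeb2 was 1.95-fold higher (0.96 ± 0.26, list-alone adjusted p = 0.0469), and Mecom, which encodes the stem cell transcription factor EVI1, was higher over a Control level below background (list-alone adjusted p = 0.0469), with 2 of 3 probe sets higher and 2 of 3 arrays labelled Runx1-KO above background. Pbx3, a HOX co-factor gene, was 2.39-fold lower (-1.26 ± 0.32, list-alone adjusted p = 0.0469). Hoxa9 was at 3193 against 2859, a log2 difference of 0.16 ± 0.16, and Meis1 at 231.5 against 161.2, a difference of 0.52 ± 0.36, and neither passed. The list call ended without Runx1-KO 2 (adjusted p = 0.0725) without Control 1 (adjusted p = 0.0615), without both arrays numbered 1 (adjusted p = 0.0997), with all probe sets (adjusted p = 0.0599), with the mean of a gene's probe sets (adjusted p = 0.0966) and with array weights (adjusted p = 0.0615). It was kept in 13 of 20 alternatives.

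Stem and progenitor markers changed singly, without a common direction. Of 19 measured members, 0 passed over all genes, 2 rose and 3 fell when adjusted over the list alone, and 14 did not pass (median -0.10, or 0 with dim genes at their bound and -0.41 to 0.19 over the alternatives, camera adjusted p = 0.645). Angpt1, the ligand of the Tie2 receptor, was at least 7.14-fold lower (list-alone adjusted p = 0.00869) with 2 of 3 arrays labelled Runx1-KO above background. Cd48, a surface protein absent from long-term stem cells, was 2.72-fold lower (-1.44 ± 0.20, list-alone adjusted p = 0.00562) and Cd93 1.74-fold lower (-0.80 ± 0.18, list-alone adjusted p = 0.0211) with 1 of its 5 probe sets higher. Procr, the endothelial protein C receptor gene expressed on stem cells, was at least 1.16-fold higher (list-alone adjusted p = 0.0211), with 2 of 3 arrays labelled Runx1-KO above background.

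Genes of cell division were lower in the arrays labelled Runx1-KO. All 28 measured G2/M and mitosis genes had a lower mean there, with a median log2 difference of -0.79 (camera adjusted p = 9.76e-09, and adjusted p = 0.653 with an estimated correlation), although 0 passed over all genes or adjusted over the list alone. The lowest p was that of the spindle checkpoint kinase gene Ttk, at -1.40 ± 0.37 (list-alone adjusted p = 0.0693), and the median was -0.47 without Runx1-KO 2. Of 28 measured G1/S and DNA replication genes, 22 were lower and 0 passed on either adjustment, with a median of -0.25 (camera adjusted p = 0.0270, and adjusted p = 0.840 with an estimated correlation). Gins1, part of the replicative helicase, had the lowest p there, at -0.73 ± 0.28. That list's call ended without Runx1-KO 2 (median -0.02, adjusted p = 0.738), without Control 1 (adjusted p = 0.0615), after quantile normalization (adjusted p = 0.107), over the brighter genes (adjusted p = 0.220) and with array weights (median -0.14, adjusted p = 0.443).

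Interferon response genes were lower, with 25 of 29 measured members lower and 0 past over all genes or adjusted over the list alone. Their median log2 difference was -0.40, or -0.30 with dim genes at their bound (camera adjusted p = 0.00454, and adjusted p = 0.797 with an estimated correlation), and the lowest p was that of Ifi35 (-0.89 ± 0.21, list-alone adjusted p = 0.136). The call ended without Runx1-KO 3 (adjusted p = 0.0573) and over the brighter genes (adjusted p = 0.114), and the median was -0.25 without Control 1 and -0.69 without Control 3.

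**Figure D3:**
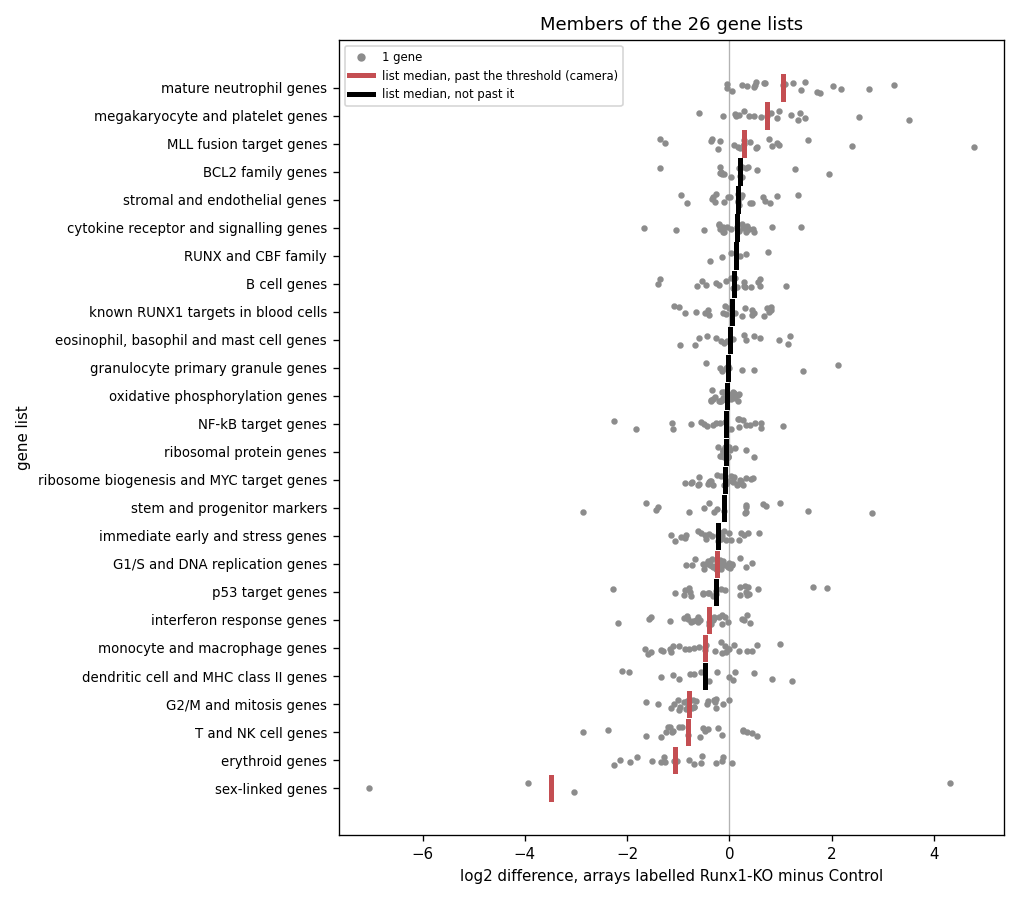
Log2 difference (arrays labelled Runx1-KO minus Control) of each measured member of the 26 gene lists (grey points) with the list medians (bars, red where the camera test passed). Medians ran from -3.49 for sex-linked genes, where fitted values of genes below background were plotted, to 1.04 for mature neutrophil genes.

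The remaining lists did not pass as lists. Of 26 measured p53 target genes, 0 passed over all genes and 2 fell when adjusted over the list alone, Ccng1, which encodes cyclin G1 (-0.77 ± 0.16, list-alone adjusted p = 0.0404), and Zmat3, an RNA-binding protein gene (at least 1.09-fold lower, list-alone adjusted p = 0.0247, above background in 2 of 3 Control arrays), while the list median was -0.26 (camera adjusted p = 0.234), with -0.13 without Control 1 and -0.40 over the brighter genes. BCL2 family genes had a median of 0.21 (camera adjusted p = 0.349), which was 0.02 with dim genes at their bound and ran from 0.00 without Runx1-KO 2 to 0.38 without both arrays numbered 1. The member past over the list alone, Bcl2l10, was below background in both groups, and Bcl2 itself had a log2 difference of -1.35 ± 0.39 (list-alone adjusted p = 0.107). Ribosome biogenesis and MYC target genes had a median of -0.09, or -0.17 to -0.04 over the alternatives (camera adjusted p = 0.349), and 1 of 30, Dkc1, which encodes the pseudouridine synthase dyskerin, fell when adjusted over the list alone (-0.87 ± 0.16, adjusted p = 0.0494). NF-kB target genes had a median of -0.06, or -0.01 with dim genes at their bound and -0.28 to 0.30 over the alternatives (camera adjusted p = 0.919), and 1 of 24, the neutrophil chemokine gene Cxcl1, rose when adjusted over the list alone (at least 1.77-fold, adjusted p = 0.0273), with 1 of 3 Control arrays above background. On the last 3 of these lists 0 members passed over all genes.

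On the other lists, 0 members passed over all genes or adjusted over the list alone. Ribosomal protein genes had a median of -0.07, or -0.09 to 0.00 over the alternatives (camera adjusted p = 0.667; lowest p in Rps6, at 0.48 ± 0.17) and passed as a list only with the ordinary statistic (adjusted p = 0.0301). Oxidative phosphorylation genes had a median of -0.05, or -0.08 to 0.00 over the alternatives (camera adjusted p = 0.427; lowest p in the complex I gene Ndufa9, at -0.32 ± 0.17). Cytokine receptor and signalling genes had a median of 0.15, or 0.03 with dim genes at their bound and -0.07 to 0.27 over the alternatives (camera adjusted p = 0.645), with the lowest p in the GM-CSF receptor gene Csf2ra (-0.49 ± 0.17). Immediate early and stress genes had a median of -0.23 (camera adjusted p = 0.529), with the lowest p in the heat shock gene Hsph1 (-0.95 ± 0.26). Their median turned to 0.15 without Control 1 and to 0.10 without Runx1-KO 3, and it was -0.03 without Runx1-KO 2, -0.49 with array weights or without Control 2, -0.40 without Control 3 and -0.15 with all probe sets. They passed as a list only without Runx1-KO 1 (median -0.88, adjusted p = 0.00970) and without both arrays numbered 1 (median -0.31, adjusted p = 0.0419). The estimated correlation gave the highest adjusted p of all alternatives for 9 of the 10 lists that passed, and 6 of the 10 passed with any 1 array left out. With fry, only the MLL fusion target and sex-linked lists among those 10 passed.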

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

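The tests of swapped arrays, of sex behind the other calls, of other blood cells in Control 1, of RNA quality, of admixed neutrophils and of the splits for genes were chosen only after the result was seen.

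In a fit over all 45101 probe sets, 31 passed the threshold, of which 7 carried no single gene symbol and lay outside the gene table. Of these 7, 3 were higher and 4 lower in the arrays labelled Runx1-KO, and 5 were above the background limit on every array of a group. A probe set shared by Phgdh and Gm6756 was higher, at 220.2, 241.1 and 173.4 in Runx1-KO 1, 2 and 3 and 20.3, 23.9 and 19.6 in Control 1, 2 and 3. Its Control 3 value lay below the background limit of that array (22.5), so no exact fold is stated. The largest fitted fall was in a probe set with no symbol, at intensities of 400.1, 562.5 and 434.2 in Control and of 1.3, 2.0 and 1.0 in the arrays labelled Runx1-KO. The latter values lay below the background limits of those arrays (17.0 to 19.6), so the rank of this fall is uncertain. All 4 lower probe sets had no symbol, with intensities of at least 60.9 in Control and at most 6.2 in the arrays labelled Runx1-KO. High signal in Control over background signal in the arrays labelled Runx1-KO was also the pattern of the Y-linked genes. The sources used here do not name the genes of these 4 probe sets.

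The ratio of 3' to 5' Gapdh signal stood out at 7.10 in Runx1-KO 1, against 2.77 to 3.02 in the arrays labelled Control. The same ratio for beta-actin was 1.11 in that array and 1.03 to 1.10 in the others, and that of middle to 5' 18S signal was 2.50 in that array and 1.72 to 1.91 in the others.

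Sex-linked genes parted the 2 groups completely, with high Xist and background Y-linked signal in the arrays labelled Runx1-KO, and lower Xist with Y-linked signal above background in Control. Single arrays swapped between the groups would place at least 1 array of each group at the levels of the other, and 0 arrays were so placed. That result follows from the complete split already seen, so it is not a separate test. X-linked genes known to escape inactivation had a median log2 difference of 0.24 (5 of 6 higher, standard error of the mean over genes 0.09). That direction goes with leukemias of opposite sex, although camera gave an unadjusted p of 0.107 for the list. The standard error over genes does not measure variation between samples. Whether sex may lie behind the 13 genes past the threshold outside the sex-linked list cannot be told apart from genotype, because 0 arrays separate them. Loss of Runx1 and an exchange of the labels of both whole groups stayed open as well, untested.

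Erythroid genes were a median of 4.07 higher on the log2 scale in Control 1 than in the mean of Control 2 and 3, with the red cell anion exchanger gene Slc4a1 at 2879 against 49.2 and 23.7 and the beta-globin gene Hbb-b2 at 4723 against 676 and 563. A candidate explanation is that the Control 1 sample held non-leukemic blood cells. Over 60 B cell, T and NK cell and MHC class II genes Control 1 was a median of 0.58 higher (mean 0.80, standard error over genes 0.14), with H2-Aa at 418 against 61.4 and 76.6. Of the 60, 35 were higher in Control 1 than in both other Controls, and Xist was highest there among the Controls. These values go with that explanation, but a standard error over genes of 1 array does not measure variation between samples. Of those 60 genes, 24 were above background in both other Controls and 3 stood on another list too. A leukemia with erythroid features was not tested and stays open.

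Mature neutrophil genes were higher in the arrays labelled Runx1-KO by a median of 1.04. RNA quality of Runx1-KO 1 is argued against as the whole cause, since the median was still 0.75 without that array, with the list past the threshold. More admixed mature blood neutrophils could also raise these genes. A second list of 18 such genes had a median of only 0.32, below the first by 0.72 (standard error over genes 0.30). That comparison was too strict, because genes already bright in Control hide a small share. The 9 members with a Control level below 269 had a median of 0.56 (standard error over genes 0.35), with 5 higher and 4 lower. The first list was not restricted in the same way, and standard errors over genes do not measure variation between samples, so neither comparison decides the question. Admixed neutrophils, sex and genotype therefore cannot be told apart as sources of this difference.

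Between the genotypes as labelled 16 genes passed, and the highest of the other ways to split the 6 arrays into 3 and 3 gave 0. For the gene lists the real split gave 10 and the highest other split 9. Each real count was reached by 1 of 10 splits, itself, and with 10 splits a share under 0.05 cannot be had.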

How the results depend on the processing

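An offset of 16 before the log, leaving out both arrays numbered 1 and leaving out the 4 measured genes of the sex-linked list were chosen only after the results were seen. Against 6 genes higher and 10 lower, counts became 17 and 26 over the brighter genes, 10 and 12 without the dimmest genes, 12 and 18 over the 34958 probe sets with 1 symbol, 39 and 65 with a variance trend and robust fitting, 27 and 44 with array weights, 17 and 19 at an adjusted p under 0.1, 25 and 39 with the offset, 1 and 1 with the ordinary statistic, 1 and 5 without the 4 measured genes of the sex-linked list and 0 and 0 without both arrays numbered 1. The filters tested fewer genes, and the last setting used fewer arrays; otherwise the cause was not tested. Leaving out 1 array at a time gave 1 gene higher and 1 to 2 lower. The replicate number as a block gave 0 and 0 genes and 10 lists, while deviations of same-numbered arrays over the brighter genes had correlations of 0.00, -0.18 and 0.08, and 1 of 6 arrays correlated best with its own number. Immediate early genes were an exception, high in both arrays numbered 1 (median deviations 0.84 and 0.91), so a shared handling of those stays open. Quantile normalization, median centring, the mean of probe sets and the fold limit kept both counts within 1.5 times. The 10 lists became 5 over the brighter genes, 0 with an estimated correlation and 2 with fry, and 7 to 11 with 1 array left out. Erythroid genes reversed to 0.16 without Control 1 (range -1.94 to 0.16 with 1 array left out) and to 0.27 without both arrays numbered 1, where the array of high erythroid signal was absent. T and NK cell genes reversed to 0.27 over the brighter genes. That setting left out dimmer members and kept the log2 difference of each remaining gene, so the reversal came from the members left out. Runx1 stayed higher in every alternative (0.61 to 1.03) and never passed, and all 63 named genes kept their direction wherever they were tested. Signal over background limited the dim genes: with the offset Mcam shrank to 0.90, Zp1 to 0.38 and Scg3 to -0.35.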

Other observations

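The gene lists of this part were chosen only after the gene table was seen and were tested on the same arrays. Their directions and p values are therefore not independent evidence, least of all for the serine list, which was built around Phgdh. Camera p values in this part were adjusted over these added lists alone, not together with the lists fixed before the data were examined.

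Serine synthesis and ATF4 target genes, which answer amino acid shortage, were higher as a list in the arrays labelled Runx1-KO. Among serine enzyme genes besides Phgdh, the log2 difference was 0.35 for Psph, 0.03 for Shmt2, -0.06 for Psat1 and -0.70 for Shmt1. Shmt1 and Shmt2 each had 1 of 4 probe sets higher. These enzymes thus did not rise together with Phgdh. Of 18 measured members 14 were higher, 1 rose and 1 fell when adjusted over the list alone, and the median log2 difference was 0.52 (camera adjusted p = 0.00307, and adjusted p = 0.435 with an estimated correlation). Trib3, a pseudokinase induced by ATF4, stood at 114.0, 1478 and 1251 in Runx1-KO 1, 2 and 3 and at 56.9, 129.2 and 136.6 in Control, so its rise lay in 2 arrays, and Runx1-KO 1 likewise stood within or below the Control range for Sesn2 (51.8 against 253.3 and 251.9) and Mthfd2 (481.2 against 939.9 and 1207). The asparagine synthetase gene Asns was at 804 against 483 (0.73). None of these passed the list-alone threshold, whereas Cebpg fell to 261 from 611 (-1.23, list-alone adjusted p = 0.0182) with 1 of its 3 probe sets higher. Of 18 measured cholesterol synthesis genes 12 were lower and 6 higher, with a median of -0.26. Camera gave an adjusted p of 0.0467 over the added lists, and of 0.537 with an estimated correlation. Because this list was chosen after the data were seen, that call was not tested independently. Sqle, the squalene epoxidase gene, fell to 26.1 from 85.0 (-1.70, list-alone adjusted p = 0.00904). Glycolysis genes had a median of -0.10 (camera adjusted p = 0.703) with Slc2a3 the 1 member past the list-alone threshold, and the X-linked escape genes and the second neutrophil list gave camera adjusted p values of 0.178 and 0.185.

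The second list of mature blood neutrophil genes moved both ways. Ifitm1 (1.30), Wfdc21 (1.68), Asprv1 (1.21) and Mxd1 (0.92) rose when adjusted over the list alone. Il1rn, the interleukin-1 receptor antagonist gene (-1.26), and Selplg, which encodes the ligand of P-selectin (-1.03), fell.

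Immediate early genes were high in both arrays numbered 1. Fos stood at 2179 in Runx1-KO 1 and 1800 in Control 1 and at 104 to 507 in the other 4 arrays, Egr1 at 2483 and 1891 against 252 to 882, and Jun at 2617 and 1926 against 322 to 756.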
